A study of Homo sapiens with 2 samples.

How the data were processed

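The samples were 2 libraries of AC16 cells, an established human cardiomyocyte cell line, 1 with the long non-coding RNA DCRT knocked out by CRISPR-Cas9 and 1 unedited. Groups were taken from the genotype labels. RNA was extracted with Trizol, per the labels' protocols. The series' design text describes PacBio long-read sequencing of isoforms, while the labels' protocols describe strand-specific paired-end Illumina libraries. The values name isoforms of each library, so they were read as long-read results, but this does not settle the conflict. Reads were aligned with minimap2 to hg38, per the submitters' processing notes. The versions, the programs that built the isoforms and called the events, the annotation release and any filters on support are not given in the sources used here.

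For each library the authors deposited 5 tables, 1 per event type, with alternative acceptor sites, alternative donor sites, exon skipping, intron retention and mutually exclusive exons. Per the file headers, each row gives the chromosome, the isoforms of each form, the gene identifier, a structure code and the splice positions. From the values, each form is carried by isoforms of the library, by annotated Ensembl transcripts or by both. Both forms were carried by library isoforms in 85.3% of DCRT-KO and 84.8% of WT events. The tables hold no read counts, inclusion levels or scores. For this reason the planned comparison of event usage in shared events, at a minimum of 20 reads, was left out, and the planned minimum of 2 reads or isoforms on each form was applied to library isoforms. How deeply each library was sequenced is unknown here. A longer list can come from more reads, and genes with higher expression yield more isoforms and more events, so numbers of events mix expression, depth and splicing. A gene absent from a list may have been expressed below detection.

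Each row was counted as 1 event. Rows that repeat the type, gene and positions of another row made up 6.94% of the DCRT-KO list and 5.40% of the WT list. Identifiers were matched to gene symbols with a table of gene names, which named 8021 of 8028 gene identifiers (99.9%). Positions were compared with GENCODE v29 on the same assembly, GRCh38, which holds 93.6% of the 15957 annotated transcripts named in the tables, so the authors used another release. An intron retention event was called annotated when its intron is an intron of any v29 transcript, and an exon skipping event when its segment is a v29 exon. Segments inside v29 exons were searched in the v29 transcript sequences for their end bases and for direct repeats at their ends, 10469 segments in all, with 5 control segments of the same length at random places in the same exon for each.

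Shares of a list are given with exact (Clopper-Pearson) 95% intervals. Differences in share and ratios are given with intervals from 1000 bootstrap draws of genes, because events of the same gene share isoforms and are not independent. For differences and ratios, intervals from event counts alone are narrower and were used only to say which alternatives moved a ratio or a share. The exact intervals of shares also treat events as independent. They decided the comparisons of end repeats with control segments and of recurring unannotated with annotated introns. All intervals cover counting error only, without the spread between cultures. Numbers of events of single genes have no error estimate here. No test of the genotypes is possible with 1 library per group, and no p-value was computed. Shared events are those with identical type, chromosome and positions. For 13 gene lists (complex I, other oxidative phosphorylation genes, mitochondrial dynamics, sarcomere and cytoskeleton, exons regulated by PTBP1, genes regulated by RBM20, splicing factors, dilated cardiomyopathy genes, calcium handling, apoptosis, ribosomal proteins, matrix and fibroblast markers, and endothelial and smooth muscle markers), the mean and median difference in events per gene were placed among 10000 random lists of the same size. Random members were drawn from genes in the same of 11 bins of total events in both libraries. The percentile describes these libraries, and 5% of random lists lie outside the central range by chance. The lists, the tests and the rule for named genes were fixed before the data were examined. Lists of epithelial and cardiomyocyte markers were added later. The rule names PTBP1, the 3 genes per event type with the largest difference in events in each direction, and the 2 members of each list with the largest absolute difference. A further gene that the rule names is not reported here.

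The statistics were tested on simulated data. With the observed totals of 8018 genes split at random between the libraries, 10 of 130 list percentiles lay outside the central range. A 2-fold shift of the odds planted in the matrix list was recovered in 10 of 10 simulations, as was a 3-fold shift. Events were split independently in these simulations, whereas real events of a gene share isoforms. The recovery therefore does not show how large a shift must be to be seen in the real lists. Of 200 random lists of 30 real genes, 8 lay outside the central range. The overlap step found 300 of 900 planted events by identical position and 600 within 10 bases, as planted. The interval from event counts for a difference in share held the true value in 282 of 300 simulations of independent events. The coverage of the gene bootstrap intervals, which are those printed with the differences, was not simulated.

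The alternatives planned before the data were examined were collapsing repeated rows, chromosomes 1 to 22 and X alone, at least 2 library isoforms on each form, genes with an event in both lists, leaving out the 10 genes with most events, boundaries within 10 bases or any overlap for shared events, thinning the DCRT-KO events to the WT number in 100 draws, distinct genes as the unit, unmatched random lists, and events scaled to the total of each type. Alternatives added after seeing the data were leaving out COL1A1, a library isoform on both forms, annotated introns alone, genes with equal isoform numbers, and thinning the DCRT-KO isoforms to the WT number in 20 draws. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.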

Results

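The series title links the long non-coding RNA DCRT to the splicing regulator PTBP1 and to dilated cardiomyopathy. The study asked whether losing DCRT goes with a different set of alternative splicing events in AC16 cells. AC16 is an established human cell line labelled as cardiomyocyte. It was compared in a form in which DCRT had been knocked out with CRISPR-Cas9 (DCRT-KO) and in its unedited form (WT). Per the series' design text, full-length transcripts were read by PacBio long-read sequencing, while the labels' protocols describe Illumina libraries. There was 1 library of each genotype, 2 libraries in all. The files list alternative splicing events of 5 types. Each event names a pair of alternative forms of a transcript segment and the isoforms that carry each form. They give no read number and no inclusion level. The depth of sequencing behind a listed event is therefore unknown, and the size of each list stands in for it. The DCRT-KO list held 42783 events and named 54197 isoforms of that library and 6729 genes. The WT list held 35307 events and named 49374 isoforms and 6407 genes. These totals include 1472 DCRT-KO and 1203 WT events formed by annotated transcripts alone. They also include 348 and 259 events at loci without a gene identifier, which are not among the counted genes. With 1 library per genotype no difference below has a replicate check, and every value describes these 2 libraries. An event missing from a list was not detected in that library, which does not show that the gene was silent or spliced otherwise. No gene in the tables used here carries the symbol DCRT, so the targeted gene itself was not analysed here and the knockout label was not checked.

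Exon skipping made up more of the DCRT-KO list than of the WT list, and intron retention made up less. Exon skipping, in which an internal exon is left out of the transcript, accounted for 16988 DCRT-KO events, or 39.7% of the list (exact 95% interval 39.2 to 40.2), against 12180 WT events, or 34.5% (34.0 to 35.0). Intron retention, in which an intron stays in the transcript, accounted for 12224 events in DCRT-KO, or 28.6% (28.1 to 29), and 12401 events in WT, or 35.1% (34.6 to 35.6). Mutually exclusive exons, the rarest type, were listed 2009 times in DCRT-KO and 1311 times in WT, 4.70% and 3.71% of the lists. Alternative acceptor sites took 15.7% and 15.5% of the lists, with 6733 and 5483 events, and alternative donor sites took 11.3% and 11.1%, with 4829 and 3932 events.

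The difference in share between DCRT-KO and WT was 5.21 percentage points for exon skipping (95% gene bootstrap interval 4.24 to 6.31), -6.55 points for intron retention (-7.51 to -5.61) and 0.983 points for mutually exclusive exons (0.639 to 1.29). The intervals of the acceptor difference of 0.208 points (-0.336 to 0.737) and of the donor difference of 0.151 points (-0.309 to 0.631) include 0. In numbers of events the DCRT-KO list was 1.21 times as long as the WT list (1.17 to 1.25). The ratio was 1.39 for exon skipping (1.36 to 1.43) and 1.53 for mutually exclusive exons (1.39 to 1.68), and for intron retention it was 0.986 (0.929 to 1.04). Counted in distinct genes rather than events, the differences were 0.896 points for exon skipping and -2.97 points for intron retention. These intervals cover the counting of events and the choice of genes, not the spread between cultures.

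**Figure D1:**
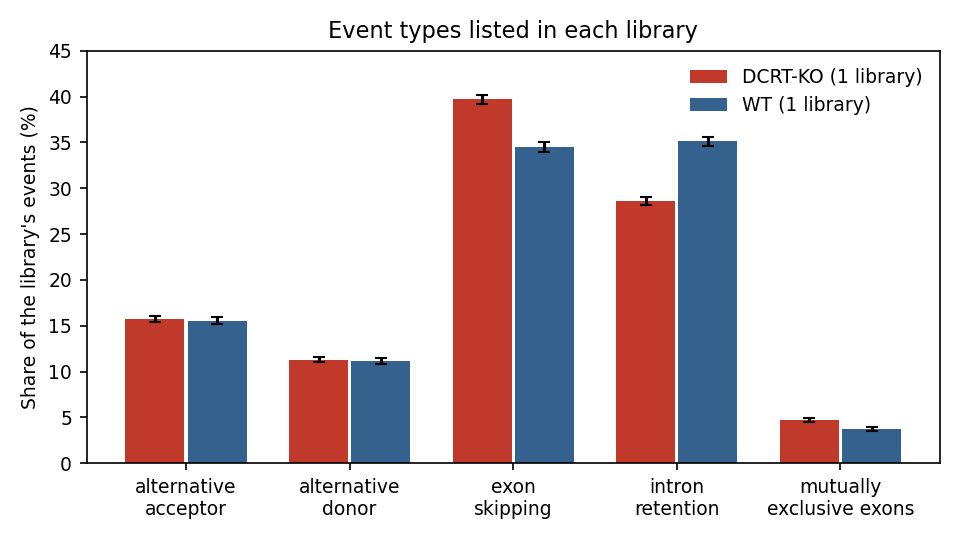
Share of each library's listed events, in percent, that fall into each of the 5 event types, for DCRT-KO (red, 1 library) and WT (blue, 1 library), with exact 95% intervals that cover counting error only. Exon skipping took 39.7% of the DCRT-KO list and 34.5% of the WT list, and intron retention took 28.6% and 35.1%.

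Most skipped exons were exons of the GENCODE v29 gene annotation, while retained introns lay outside that annotation slightly more often than in it. The skipped segment matched an annotated exon in 75.9% of DCRT-KO and 75.0% of WT exon skipping events. These exons had a median length of 113 bases in DCRT-KO and 111 bases in WT. Their length was a whole number of codons in 43.2% (42.4 to 44.1) and 44.6% (43.6 to 45.6), against 33.3% for random lengths. Annotated exons that were not skipped were not counted, so no comparison with exons in general is given. The form with the exon was annotated and the form without it was not in 30.3% of DCRT-KO events (29.6 to 31.0) and 27.0% of WT events (26.2 to 27.8). Among alternative acceptor events, 7.68% in DCRT-KO (7.05 to 8.34) and 8.68% in WT (7.95 to 9.46) joined sites 3 bases apart, a known kind of tandem acceptor.

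Retention of an annotated intron made up 5888 of the DCRT-KO intron retention events (48.2%, 47.3 to 49.1) and 5814 of the WT events (46.9%, 46.0 to 47.8). These introns had medians of 354.5 and 353 bases. The other 6336 DCRT-KO and 6587 WT events rested on an intron that GENCODE v29 does not list. Of these segments, 81.2% in DCRT-KO and 82.8% in WT lay inside an annotated exon. The spliced form was carried by a single library isoform in 96.2% and 96.6% of them. Inside exons, only 15.3% of the DCRT-KO segments (14.3 to 16.3) and 12.4% of the WT segments (11.5 to 13.3) had the GT and AG ends of ordinary introns. With annotated introns alone counted as intron retention, the difference in its share was -4.09 percentage points and that of exon skipping 4.20 points.

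COL1A1, the main chain of type I collagen, separated the lists more than any other gene named by the rule fixed in advance. The gene (ENSG00000108821, hg38 chromosome 17, 50183289 to 50201632) held 405 events in WT and 1 in DCRT-KO. The difference ran through every type, with 179 WT intron retention events, 89 acceptor, 77 donor, 35 exon skipping and 25 mutually exclusive exon events. The WT events of COL1A1 were carried by 772 isoforms and the DCRT-KO event by 1 isoform. SPARC, a matrix protein that binds collagen, held 58 events in WT and 4 in DCRT-KO, and COL1A2, the partner chain of COL1A1, held 31 in WT and 0 in DCRT-KO.

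The other genes with more events in WT were of mixed function. The cytoplasmic actins ACTB and ACTG1 held 279 and 204 events in WT and 126 and 97 in DCRT-KO. Their sequences are close to each other and to several pseudogenes, so the split between them is uncertain. For exon skipping they were MARCHF7, a ubiquitin ligase, with 17 WT and 2 DCRT-KO events, and CPT1C, a carnitine palmitoyltransferase family member, with 12 WT and 0 DCRT-KO events. For mutually exclusive exons they were TMBIM6, an endoplasmic reticulum protein, with 19 and 5 events, and PLS3, an actin-bundling protein, with 14 and 3 events. The 2 DCRT-KO events of MARCHF7 were formed by annotated transcripts alone, with 0 isoforms of the library.

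More events were listed in DCRT-KO for HSPA8, the constitutive heat shock cognate of the HSP70 family, with 197 events against 57 in WT, of which 145 and 42 were intron retention. HSPA8 has many processed pseudogenes, so its values are uncertain. EIF4A2, an RNA helicase of translation initiation, held 120 and 43 events. PHGDH, the first enzyme of serine synthesis, held 77 and 4, and PLAU, the urokinase plasminogen activator, 63 and 1. UBAP2L was named for both acceptor and donor sites, with 20 DCRT-KO and 5 WT events in each type. COPB1, a coat protein of transport vesicles, held 24 donor events in DCRT-KO and 4 in WT, and RANGAP1, the GTPase activator of nuclear transport, held 22 and 6. For exon skipping the genes were VEPH1 with 24 and 3 events, ARIH2 with 41 and 21, and NBPF9 with 24 and 5. For mutually exclusive exons they were ARIH2 with 25 and 7 events, SHLD2 with 24 and 6, and HNRNPC with 11 and 2. NBPF9 and SHLD2 have near-identical copies elsewhere in the genome and are uncertain. Events of a gene share isoforms, and more isoforms give more events, such as the 112 DCRT-KO against 9 WT isoforms of PHGDH, so these numbers cannot be read as rates of splicing.

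**Figure D2:**
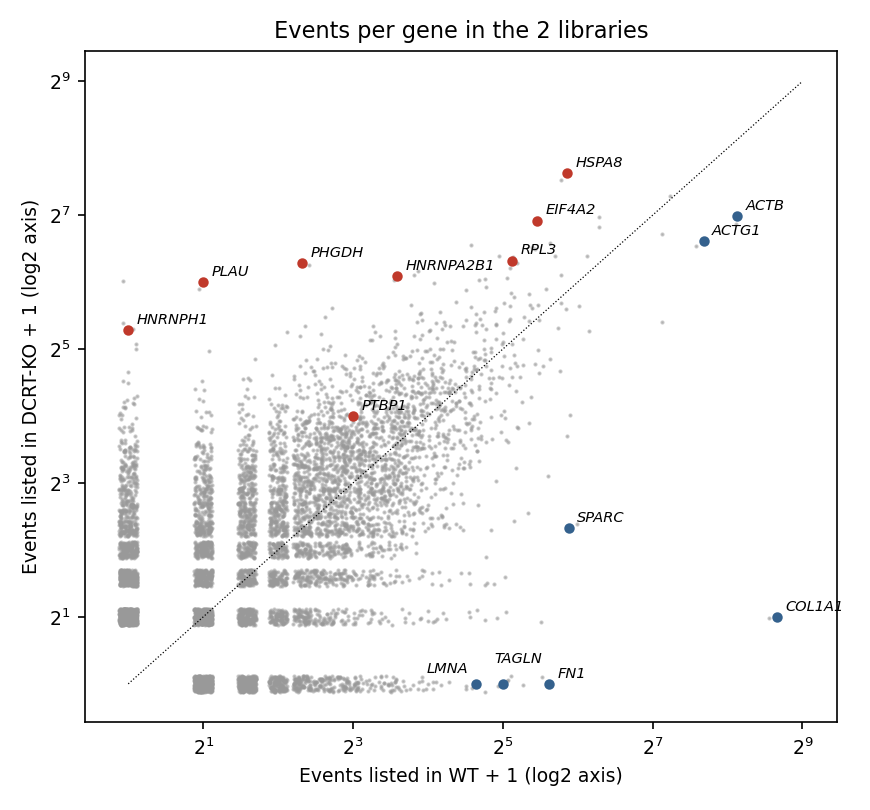
Events listed per gene in WT (horizontal, log2 axis, events + 1) against DCRT-KO (vertical, log2 axis, events + 1), 1 grey point per gene with a symbol, with small random offsets to separate overlapping grey points. Named genes are drawn without offset, red above and blue below the dotted line of equal numbers, and COL1A1 lies farthest to the right at 405 WT events and 1 DCRT-KO event.

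The lists overlapped more in genes than in events, which follows largely from a gene counting as shared through any of its events. Overlap of genes is given as a share of the genes in either list, and overlap of events as a share of each list's rows. Of 8028 genes with any event, 5108 (63.6%, 62.6 to 64.7) had an event in both lists, 1621 in DCRT-KO alone and 1299 in WT alone. Exon skipping genes were shared most often, 3641 of 6695 (54.4%), and genes with mutually exclusive exons least often, 376 of 1496 (25.1%). Genes with intron retention were listed in DCRT-KO alone 1248 times and in WT alone 1316 times, the only type with more on the WT side. An event of identical type, chromosome and positions was found in the other list for 30.6% of DCRT-KO events (30.1 to 31.0) and 35.7% of WT events (35.2 to 36.2). That share was 37.4% and 49.6% for exon skipping, and 23.4% and 22.6% for intron retention. Counting any overlap of events of the same type and gene gave 44.3% and 50.4%. Across the 5106 genes with a symbol and an event in both lists, the numbers of events had a Spearman correlation of 0.568, taken across genes, which are not independent replicates.

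Some genes with many events in a list had none in the other, in both directions. There were 61 genes with at least 10 events in DCRT-KO and 0 in WT, and 51 with at least 10 in WT and 0 in DCRT-KO. HNRNPH1, a splicing factor used by most cells, held 38 events in DCRT-KO and 0 in WT. LMNA, which encodes the lamins A and C of the nuclear envelope, held 24 events in WT and 0 in DCRT-KO. CALM3, a calmodulin gene, held 17 in WT and 0 in DCRT-KO. Only 1 of the 61 and 5 of the 51 genes had an event of the other list, under another gene's name, inside their span.

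Genes of the extracellular matrix and fibroblasts, and of the cytoskeleton, held more events in WT. Of 30 listed matrix and fibroblast genes, 23 held more events in WT and 6 more in DCRT-KO. There were 757 events in WT and 140 in DCRT-KO, and 16 members were listed in WT alone against 3 in DCRT-KO alone. FN1, which encodes fibronectin, held 48 events in WT and 0 in DCRT-KO, and LOXL2, a collagen cross-linking enzyme, held 69 in WT and 41 in DCRT-KO. CD44, a hyaluronan receptor, went the other way with 39 in DCRT-KO and 13 in WT, as did the integrin ITGB1 with 23 and 2. FN1, LOXL2, CD44 and ITGB1 were chosen after their values were seen. Of 27 listed sarcomere and cytoskeleton genes, 20 held more events in WT and 5 in DCRT-KO. The members that made up this list's events were actins, filamins, tropomyosins and other cytoskeletal genes of non-muscle cells as well as muscle, such as FLNA with 60 WT and 16 DCRT-KO events and TPM1 with 23 and 8. Of 8 endothelial and smooth muscle markers, 7 held more events in WT, among them the actin-binding genes TAGLN with 31 WT and 0 DCRT-KO events and SMTN with 33 and 14.

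The mean difference per gene, DCRT-KO minus WT, was -20.6 events in the matrix and fibroblast list, -18 in the sarcomere and cytoskeleton list and -6.63 in the endothelial and smooth muscle list. Over all 8018 genes with a symbol it was 0.922. Bootstrap intervals over the members of these lists were -50.1 to -3.20, -31.7 to -6.78 and -15.4 to 0.5, in that order. The last includes 0. Among 10000 random lists matched on events per gene these means lay at percentiles 0.04, 0.1 and 0.215, and the medians of -4, -5 and -3 events at percentiles 0, 0 and 0.185. The means rest heavily on the genes with most events. COL1A1 held 405 of the 757 WT matrix events, and the matrix mean was -7.34 without it (percentile 0.08). The cytoskeleton mean was -9.04 without the 10 genes with most events and -9.37 with annotated introns alone. With genes in both lists the matrix mean was -42.5 over 11 members. COL1A1 is among them through its 1 DCRT-KO event against 405 in WT. That mean therefore rests mostly on COL1A1, was not computed without it, and does not show a stronger pattern among genes listed in both. With at least 2 library isoforms on each form the matrix mean was -4.43 over 14 members (percentile 0.03). The cytoskeleton mean was then -2.15 over 20 members (percentile 0.8). The endothelial and smooth muscle mean was then -2 over 3 members, inside the central range at percentile 7.04. The isoforms behind the matrix events numbered 1666 in WT and 191 in DCRT-KO. Epithelial markers, a list added after the data were seen, held 97 events in DCRT-KO and 26 in WT. Only 9 of its 33 genes were listed in either library. Most of the DCRT-KO events were those of KRT18, with 38 against 16 in WT, and LAMB3, with 35 against 3. ITGA6 is a member of this list and of the matrix list. Of the markers of contracting heart muscle in a second added list, only NPPB with 2 events and MYL3 with 1 were listed, both in WT.

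**Figure D3:**
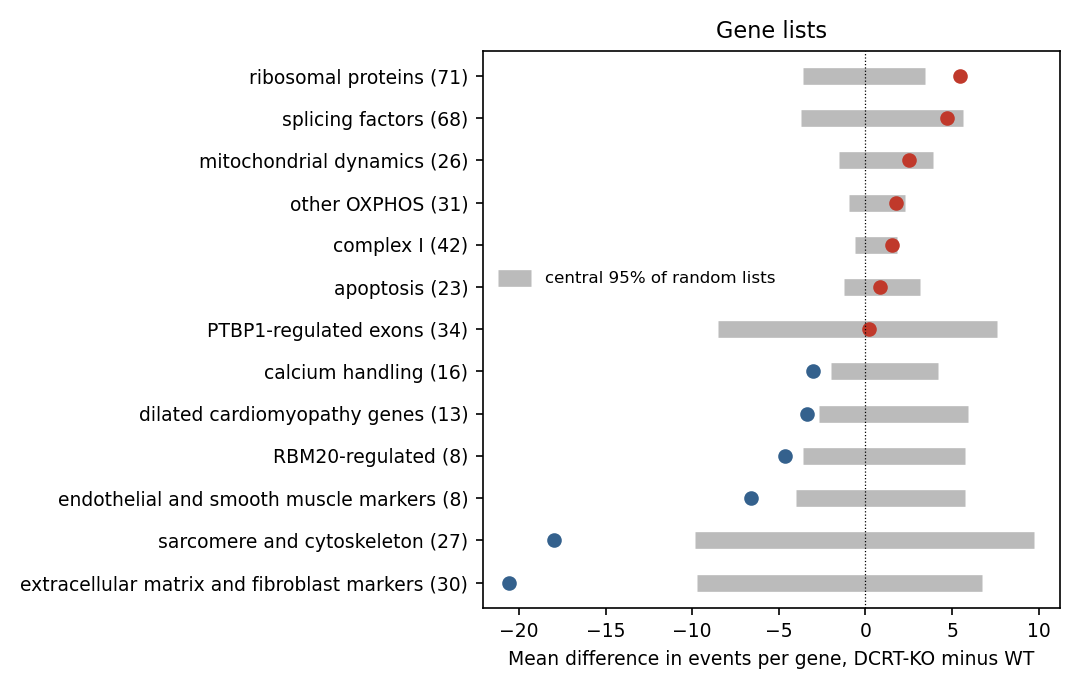
Mean difference in listed events per gene, DCRT-KO minus WT, for the 13 gene lists (number of listed members in brackets, 1 library per genotype), as points in red above 0 and blue below 0. Grey bars span the central 95% of 10000 random lists matched on events per gene. The ribosomal protein list lies above its bar and 6 lists lie below theirs, down to -20.6 for extracellular matrix and fibroblast markers.

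Ribosomal protein genes held more events in DCRT-KO. Of 71 listed members, 53 held more events in DCRT-KO and 13 in WT, with 650 events against 263. RPL3 held 79 events in DCRT-KO and 34 in WT and RPLP0 68 and 26. The mean difference of 5.45 events per gene lay above all 10000 random lists, at percentile 100, as did the median of 3. With at least 2 library isoforms on each form the mean was 1.53 over 19 members, inside the central range at percentile 96.7. The difference was seen in annotated introns as well, with 190 retention events in DCRT-KO and 104 in WT. Ribosomal protein genes have many processed pseudogenes, so the assignment of their isoforms is uncertain.

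Genes of the mitochondrial respiratory chain also held more events in DCRT-KO, within the range of matched random lists. Among complex I subunits and assembly factors, 24 of 42 held more events in DCRT-KO and 11 in WT, with 164 and 100 events. NDUFV1, the subunit that binds NADH, held 27 and 11 events and the assembly factor FOXRED1 19 and 3. The mean difference of 1.52 lay at percentile 93.3. Among the other respiratory complexes, 19 of 31 members held more events in DCRT-KO and 7 in WT, with the ATP synthase subunits ATP5F1A at 11 and 1 and ATP5F1B at 15 and 6, and the mean of 1.77 lay at percentile 91.0. Among genes of mitochondrial dynamics, 20 of 26 held more in DCRT-KO and 5 in WT. OPA1, which fuses inner membranes, held 19 and 7 events and DNM1L, which divides mitochondria, held 19 and 9, and the mean of 2.5 lay at percentile 81.7.

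Splicing factors held 987 events in DCRT-KO and 667 in WT, with 43 of 68 members higher in DCRT-KO and 21 in WT. HNRNPA2B1 held 67 and 11 events, and its 11 WT events were formed by annotated transcripts alone with 0 isoforms of the library. The mean of 4.71 lay at percentile 91.6, and at percentile 99.96 among random lists not matched on events per gene. In numbers of events, genes with exons known to be regulated by PTBP1 showed no common direction. All events anywhere in these genes were counted, and the regulated exons themselves were not located. The values therefore do not show whether splicing of those exons differed. Of 34 members, 18 held more events in DCRT-KO and 15 in WT, with 556 and 549 events. The translation factor EIF4G2 held 90 events in DCRT-KO and 41 in WT, and FLNA stood opposite as given above. The mean of 0.206 lay at percentile 17.2. Their exon skipping events numbered 152 in DCRT-KO and 119 in WT, at percentile 24.2.

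Among the remaining heart-related lists, genes regulated by the cardiac splicing factor RBM20 held 32 events in DCRT-KO and 69 in WT over 8 members, 3 higher in DCRT-KO and 5 in WT, with LMO7 at 4 and 18 and TPM1 at 8 and 23 making up most of the gap. Genes of inherited dilated cardiomyopathy held 80 and 124 events over 13 members, 6 higher in DCRT-KO and 7 in WT. Most of that gap came from LMNA, with 0 DCRT-KO and 24 WT events, and TPM1. Calcium handling genes held 78 and 126 events, with 11 of 16 members higher in WT and 4 in DCRT-KO, among them CALU, a calcium-binding protein of the secretory pathway, at 13 and 27. The means of -4.63, -3.38 and -3 events lay at percentiles 1.17, 1.38 and 0.765. Their bootstrap intervals over members were -10.25 to 0.375, -8.46 to 1.15 and -6.19 to -0.188. Those of the RBM20 and dilated cardiomyopathy lists include 0. The medians of -1.5, -2 and -2 events lay at percentiles 4.2, 2.2 and 1.04, so that of the RBM20 list was inside the central range. With at least 2 library isoforms required on each form, the calcium handling mean was 0.833 and the dilated cardiomyopathy mean 0.375, opposite in direction, and the RBM20 mean was -1.4, inside the central range at percentile 4.56. Apoptosis genes held 122 and 103 events, with BAX at 7 and 16 and BAK1 at 12 and 6, and a mean of 0.826 at percentile 40.9, which was -0.298 with events scaled to the WT total of each type. In all, 7 of 13 lists lay outside the central 95% of random lists, 1 above and 6 below, and 8 did among unmatched random lists. Lists share members, such as TPM1 in the sarcomere, PTBP1, RBM20 and dilated cardiomyopathy lists, so they are not independent.

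PTBP1, the pyrimidine tract binding protein that represses exons (ENSG00000011304, hg38 chromosome 19, 797075 to 812327, plus strand), held 15 events in DCRT-KO and 7 in WT. Both lists held skipping of the annotated exons at 799413 to 799443 (31 bases), 805492 to 805569 (78 bases) and 806408 to 806556 (149 bases). The 78-base exon was left out by 5 and included by 13 library isoforms in DCRT-KO. In WT it was left out by 0 and included by 9, the form without it being an annotated transcript. DCRT-KO alone listed skipping of the 34-base annotated exon at 807869 to 807902, left out by 2 isoforms and included by 20. Of the PTBP1 intron retention events, 8 were in DCRT-KO and 2 in WT, and all of them lay inside annotated exons on introns that GENCODE v29 does not list, each spliced in 1 isoform. The events were carried by 33 DCRT-KO and 21 WT isoforms, and numbers of isoforms are not numbers of molecules.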

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

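Among the tests below, those of COL1A1 alone, of longer WT lists, of randomly missing loci, of another cell population, of thinned isoforms, of genes with equal isoform numbers and of introns that GENCODE v29 lacks were chosen after the result was seen.

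Some events were counted in the lists but not examined as groups of their own. Events on the mitochondrial chromosome, whose genes have no introns, numbered 19 in DCRT-KO and 7 in WT. They fell in MT-ND4 with 10 and 0 events, MT-CO1 with 9 and 4, and MT-CYB with 0 and 3. Loci without a gene identifier held 348 events in DCRT-KO and 259 in WT. Events formed by annotated transcripts alone, with no library isoform on either form, numbered 1472 in DCRT-KO and 1203 in WT, 3.44% and 3.41% of the lists.

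Matrix and fibroblast genes held more events in WT, with 757 events against 140. COL1A1 supplied much of the size of the pattern, as the mean difference was -20.6 events with it and -7.34 without it, but was not the whole of it, since the latter lay at percentile 0.08, nor was the pattern due to longer WT lists, since DCRT-KO had 1.21 times as many events. The excess of 16 WT-only over 3 DCRT-KO-only members lay at percentile 100 of matched random lists, more than loci missing at random would give. No event of the DCRT-KO list fell inside the span of those 16 genes. They were picked for having no DCRT-KO events, so the empty spans add no support. A different cell population in one library, such as a clone or culture of more epithelial kind, cannot be told apart from the genotype with 1 library each, and the epithelial markers, with their mean difference at percentile 95.2 and their median at percentile 99.1, leave it open, with LAMB3 at 35 DCRT-KO and 3 WT events, KRT18 at 38 and 16 and KRT15 at 12 and 0, while KRT17 and JUP went the other way. An effect of the knockout on matrix gene expression may give the same values and was not tested.

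Exon skipping took a larger and intron retention a smaller share of the DCRT-KO list. A larger total of DCRT-KO isoforms did not account for it, since the intron retention difference with DCRT-KO isoforms thinned to the WT number was -6.99 percentage points (range over 20 draws -7.11 to -6.91), nor did a few genes with many events, since it was -6.24 points without the 10 genes that held most. In genes with equal isoform numbers in both libraries, it was smaller, -3.44 points (gene bootstrap -5.53 to -1.31), with 3.99 points for exon skipping (2.06 to 6.09), so differences in isoforms per gene may account for part of it. Introns that GENCODE v29 lacks were not the whole of it, since retention of annotated introns as a share of all events still differed by -2.70 points (gene bootstrap -3.31 to -2.13), but that is smaller than the -6.55 points of all retention events. Read depth and RNA quality, which the files do not give, and the genotype stay open as untested causes.

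More than 50% of intron retention events rested on an intron that GENCODE v29 lacks, 51.8% in DCRT-KO and 53.1% in WT. Newer annotation did not account for them, since 6.53% of the DCRT-KO events recurred in WT against 41.6% for annotated introns and 35.0% for annotated introns with a form carried by 1 isoform, and 0.331% were spliced in any annotated transcript named in the DCRT-KO tables. Template switching at repeats during reverse transcription is a candidate explanation for part of them, since a direct repeat of at least 6 bases stood at the ends of 24.8% of DCRT-KO and 24.2% of WT segments inside exons, against 1.55% and 1.52% of control segments. The aligner's placement of gaps in repeats was not separated from it, and most of these segments had no such repeat. The 15.3% of DCRT-KO and 12.4% of WT segments with GT and AG ends, against 0.450% and 0.374% of controls, may include true introns, and no biological explanation was tested.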

How the results depend on the processing

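Alternatives without COL1A1, with a library isoform on both forms, with annotated introns alone, with genes of equal isoform number and with thinned isoforms were chosen after seeing the data. Of 239 values under alternatives, 191 stayed within the interval or 1.5 times the count of the deposited lists, 46 moved and 2 reversed. Many of the 191 could hardly move, so the tally does not measure robustness. Leaving out COL1A1 cannot change the mean of a list that lacks it, and random thinning of events keeps the shares on average. Reversed is a change of sign of a difference whose interval excludes 0 or of a list outside the central range. The acceptor and donor differences, whose intervals include 0, and the apoptosis and PTBP1 list means, inside the central range, also changed sign in some alternatives (down to -2.18, -0.441, -0.474 and -2.09). The intervals used for this were those of event counts (1.19 to 1.23 for the ratio), narrower than the gene bootstrap intervals, and for list means the wide bootstrap interval over members. The exon skipping difference stayed above 0 (0.896 to 5.85) and the intron retention difference below 0 (-7.52 to -2.97) in all 12 alternatives run for them. The matrix and the cytoskeleton lists lay outside the central range in 11 of 11 settings, and the ribosomal and RBM20 lists in 10 of 11, calcium handling and dilated cardiomyopathy in 9 of 11, endothelial and smooth muscle markers in 9 of 10. Splicing factors lay outside in 1, the unmatched random lists, where 8 lists were outside. Calcium handling lay at percentile 4.18 with annotated introns alone and dilated cardiomyopathy at 4.57 with genes in both lists. Where no cause is given below, the cause was not tested.

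With at least 2 library isoforms on each form, which left 5581 DCRT-KO and 4000 WT events, the share differences were -2.18 points for acceptors, 1.22 for donors, -5.50 for intron retention and 0.654 for mutually exclusive exons. The ratio of events was 1.40, the shared part of the WT list 40.8%, and 1004 genes were in both lists, 995 in DCRT-KO alone and 682 in WT alone. Outside the central range lay 2 lists. The mean differences reversed for calcium handling (0.833) and dilated cardiomyopathy genes (0.375), and were -2.15 for the cytoskeleton, 1.53 for ribosomal proteins, 1.33 for splicing factors, 0.667 for mitochondrial dynamics and 0.600 for other respiratory genes. Fewer events per gene shrink these means by construction, while the cause of the 2 reversals was not tested.

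With repeated rows collapsed the ratio was 1.19 and the shared parts 28.1% of DCRT-KO and 33.4% of WT. With genes in both lists the shared parts were 34.2% and 39.7%. Without the 10 genes the ratio was 1.24 and the shared part of WT 36.6%. With a library isoform on both forms the intron retention difference was -7.52 and the shared parts 25.6% and 30.0%. With annotated introns alone the differences were -0.618 for acceptors, -0.441 for donors, 4.20 for exon skipping and -4.09 for intron retention, the ratio 1.27 and the shared parts 34.8% and 42.5%. In genes with equal isoform numbers they were -1.51 for acceptors, 3.99 for exon skipping and -3.44 for intron retention, with a ratio of 1.11. Boundaries within 10 bases gave shared parts of 31.8% and 37.0%, and any overlap 44.3% and 50.4%. Counted in distinct genes the differences were 0.896 for exon skipping, -2.97 for intron retention and 1.58 for mutually exclusive exons. Thinned events have a ratio of 1 by construction, and thinned isoforms gave 1.11. With events scaled to each type's total the mean for mitochondrial dynamics was 1.06. Minimums of 10 and 50 reads could not be run without reads, and no library could be left out with 1 per group. No paired analysis was possible because each group has 1 library. The unknown read depth limits every statement about events in a single list.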

Other observations

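No test was chosen for this part, and the genes below were picked after their values were seen. Other secreted or surface proteins listed in WT alone were LGALS3BP with 40 events, CPA4 with 23, THBS1 with 22, COL3A1 and FAP with 12 each, and MATN2 with 15. Genes listed in DCRT-KO alone included the transporter SLCO4A1 with 40 events, the tumour antigen gene PRAME with 33, the cyclin CCND1 with 30, the transcription factor KLF6 with 22, the splicing factor SF3B1 with 19 and FGFR4 with 14.

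Retention of annotated introns, with 5888 events in DCRT-KO and 5814 in WT over all genes, was not tested between lists of genes. Splicing factors held 187 such events in DCRT-KO and 145 in WT, complex I genes 39 and 25, other respiratory genes 20 and 18, and genes with exons regulated by PTBP1 62 and 83. Matrix and fibroblast genes held 7 and 77, and cytoskeleton genes 59 and 104. EIF4A2 held 63 and 30, HSPA8 31 and 11, PLAU 19 and 0, and HNRNPH1 15 and 0. COL1A1 held 1 and 52.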
